A study of Mus musculus with 17 samples.

How the data were processed

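Total RNA from bone marrow was isolated with the RNeasy Micro kit with DNase digestion, and libraries were made with the v2 Pico version of a SMARTer stranded total RNA kit (Takara), per the labels' protocols. This kit marks strand and takes very small amounts of RNA. Per the submitters' processing notes, Trimmomatic 0.35 and RSEM 1.3.3 were used, with the builds GRCm38 and mm10, which name the same assembly; their roles and settings, the aligner and the strand setting are not given in the sources used here. The authors deposited whole-number counts per gene, not normalized, in a table of 17 libraries and a table of 6 summed columns. RSEM estimates need not be whole, and how whole numbers were reached is not given in the sources used here. Each summed column was tested against the libraries that its header names, and it equalled their sum in every gene, with 0 genes differing in all 6. The tables list 56305 gene identifiers with symbols, of which 55141 matched the GENCODE vM21 annotation of GRCm38, from which coordinates were taken. Where a listed symbol has several identifiers, the one with the highest total count was used.

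Groups were taken from the sample titles, which give 8 control and 9 Mt1ko libraries. The titles number libraries 1 to 18 without 13, which was not analysed here. The unit of replication, the test, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule used the summed table where its columns show the group, so 3 control and 3 Mt1ko samples entered the comparison. Because the labels call every library a technical replicate, the 17 libraries served as an alternative, and the sums are the more careful unit.

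Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the quasi-likelihood F test with group alone in the model. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. TMM factors were 1.00 to 1.05 in 5 samples and 0.85 in Mt1ko sample 10-12. Standard errors are the log2 fold change divided by the root of F, and 95% intervals use the test's degrees of freedom. CPM of summed samples are TMM-scaled, and CPM of libraries are relative to all counts. Log2 values of libraries used a pseudocount of 1 CPM for Xist and the list scores, and none for the permutation tests of Mt1 and Mt2. Correlations between libraries instead used TMM-scaled log2 CPM with a prior count of 1. Of 31 lists, the 30 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. The lists held 702 distinct genes, of which 584 were tested. List shifts per sample are medians over members of log2(CPM + 1) less the control mean.

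Named genes were Mt1, Mt2, Dnmt3a and Npm1, then the 10 largest rises and falls among called genes with an average log2 CPM of at least 1, leaving out predicted loci. If fewer than 5 genes passed in a direction, the 5 with the smallest p were named as values that did not pass; the conditions on expression and symbol were read as applying to them too. Up to 4 members were named of each called list. Marker genes named to describe cell identity, library quality and sample differences (such as Lyz2, Itgam, Csf1r, Hoxa9, Meis1, Cpa3, Kit, Mrc1, Chil3, Elane, Xist and the genes of the Y chromosome) lie outside this rule and were chosen after their values were seen.

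Mt1 and Mt2 were also compared with exact permutation tests of mean log2 CPM. Libraries were compared by Spearman and Pearson correlation, and by chi-square against sampling noise over genes with at least 50 counts per pair. The lowest chi-square per gene of any pair was 32.4, where sampling noise alone gives about 1, so no library repeated another. The test was run on simulated counts with means, library sizes and spread of the 6 samples and 200 changed genes, 50 per fold size; it made 159 calls among 15820 genes, of which 4 were false. The common biological coefficient of variation was 0.67, and the median over 4955 genes with an average log2 CPM of 5 or more was 0.188.

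Alternatives were RLE and upper quartile scaling, no filter and a stricter filter (1 CPM in every sample of a group), the 17 libraries with and without the second index sequence as a covariate, DESeq2 1.42.0, limma-voom, thresholds of 0.01 and 0.10, and leaving out each summed sample. Alternatives chosen after the data had been seen left out library 6, library 6 with libraries 10 to 12, or the mitochondrially encoded genes, used the summed sample as a random effect over 17 libraries, or weighted samples by quality. Intervals and limits of detection cover counting error and the spread between these samples only, and PCR copies cannot be told from separate molecules here.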

Results

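Bulk RNA was profiled from the bone marrow of C57BL/6 mice with acute myeloid leukaemia (AML) carrying a heterozygous Dnmt3a point mutation and the heterozygous Npm1cA allele. Dnmt3a encodes a de novo DNA methyltransferase, and the Npm1cA allele encodes a form of nucleophosmin that is retained in the cytoplasm. The series asked how transcription differed when Mt1 had been knocked down with CRISPR-Cas9. Mt1 encodes metallothionein 1, a small cysteine-rich protein that binds zinc and copper. Of the 17 libraries, 8 were labelled control and 9 were labelled Mt1ko, and every library was labelled a technical replicate. The authors' summed table joined them into 6 samples. The control samples were the sums of libraries 1-3, 7-9 and 14-15, and the Mt1ko samples were the sums of libraries 4-6, 10-12 and 16-18. Library totals ranged from 27124722 to 38645072 counts, and the summed samples held between 64247249 and 106407001 counts. Nothing states that the 6 samples came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

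The targeted gene was examined first, in every library. Mt1 was low in 8 of the 9 libraries labelled Mt1ko, at 41.8 to 87.2 CPM (counts scaled to the library total), against 347.5 to 471.3 CPM in the 8 control libraries. The median of those 8 libraries was 20.6% of the control median. Library 6, which was labelled Mt1ko, went against its label: it held 326.2 CPM of Mt1, or 84.7% of the control median, from 12606 counts. Libraries 4 and 5, which were summed with it, held 82.7 and 86.2 CPM. The name Mt1ko 4-6 is therefore used as the label of a sample that contains the library labelled Mt1ko with control-level Mt1, and directions drawn from it carry that limit.

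**Figure D1:**
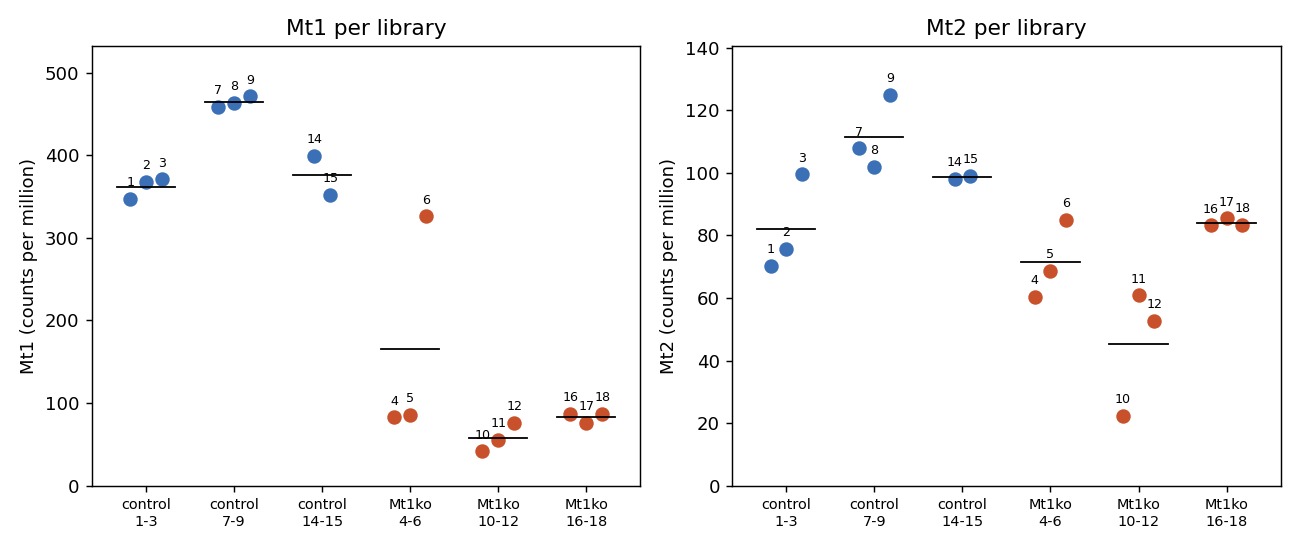
Mt1 (left) and Mt2 (right) as CPM relative to all counts (vertical axes), for each of the 17 libraries, grouped by summed sample. Points are libraries (blue control, orange Mt1ko) with their library numbers, and black lines are the means of the libraries in a sample. Library 6, labelled Mt1ko, lies at 326.2 CPM for Mt1, near the control libraries at 347.5 to 471.3 CPM.

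On the 6 summed samples, Mt1 (ENSMUSG00000031765; GRCm38 chromosome 8, 94179082 to 94180327, plus strand, protein-coding) was 384.2 ± 49.2 CPM in control and 106.8 ± 56.8 CPM in Mt1ko (SD, n = 3 each). Every Mt1ko sample lay below every control sample. The log2 fold change was -1.85 (SE 0.34, 95% interval -2.64 to -1.05), with the smallest p of all genes tested (edgeR quasi-likelihood adjusted p = 1). The gene did not pass the threshold over all genes, and it passed when adjusted over the list alone (2 tested metallothioneins, edgeR adjusted p = 0.0015). An exact two-sided permutation test on the 6 samples gave p = 0.1, the smallest that 3 against 3 samples allow. Over the 17 libraries the exact p was 8.23e-05, but libraries of 1 sample are not independent. The libraries also carried 3 second index sequences. Mt1 averaged 401.7 CPM in 5 control libraries and 165.0 CPM in 3 Mt1ko libraries with the first, and 407.6 CPM in 3 control libraries and 65.2 CPM in 4 Mt1ko libraries with the second. The 3 Mt1ko libraries with the first index were all of sample 4-6, at 82.7, 86.2 and, in library 6, 326.2 CPM, and at most 2 samples stood behind any of these means, so a p-value over libraries would not be valid and none is given. The third index was carried only by 2 Mt1ko libraries. With library 6 left out of its sum, Mt1 was 77.7 ± 8.9 CPM in Mt1ko (SD, n = 3), the log2 fold change was -2.30 (SE 0.16) and the gene was called (edgeR adjusted p = 0.010). That library was left out because of its Mt1 value, so this p is not independent evidence.

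Mt2 (ENSMUSG00000031762; chromosome 8, 94172664 to 94173568, plus strand), the paralog that ends 5513 bases upstream of Mt1, was 93.1 ± 12.5 CPM in control and 69.2 ± 14.1 CPM in Mt1ko (SD, n = 3 each). Its log2 fold change of -0.43 (SE 0.19, 95% interval -0.86 to 0.0041) did not pass the threshold (edgeR quasi-likelihood adjusted p = 1). The exact permutation p was 0.2 on the 6 samples. Over the 17 libraries it was 0.00621, with the same limit on independence. Mt3 and Mt4 were not among the tested genes. Mt1 and Mt2 are related in sequence, and how the counting treated reads shared by them is not given in the sources used here.

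The 2 genes of the leukaemia's genotype were not called. Npm1 (ENSMUSG00000057113; chromosome 11, 33152287 to 33163206, minus strand) was 257.2 ± 18.4 CPM in control and 287.7 ± 30.1 CPM in Mt1ko, a log2 fold change of 0.16 (SE 0.13; edgeR adjusted p = 1). Dnmt3a (ENSMUSG00000020661; chromosome 12, 3806007 to 3914443, plus strand) was scarce, at 2.70 ± 1.41 CPM in control and 6.74 ± 9.44 CPM in Mt1ko (SD, n = 3 each). Its log2 fold change of 1.32 (SE 1.04; edgeR adjusted p = 1) came from Mt1ko sample 10-12 at 17.6 CPM, since the other Mt1ko samples held 1.29 CPM each. Without that sample the log2 fold change was -1.06.

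Both groups had transcripts of monocytes and macrophages, and whether leukaemic or normal cells made them was not tested. Of the 25 monocyte and macrophage markers, 16 averaged at least 10 CPM in the control samples and 8 under 1 CPM. Lyz2, which encodes lysozyme, was 3479 ± 1882 CPM in control and 3562 ± 891 CPM in Mt1ko. Itgam, which encodes the integrin CD11b, was 2982 ± 177 and 3006 ± 690 CPM, and Csf1r, the receptor for colony stimulating factor 1, was 391.5 ± 43.7 and 360.8 ± 100.3 CPM (SD, n = 3 each). Of the 23 genes of the HOX/MEIS leukaemic programme, 6 averaged at least 10 CPM in control and 10 under 1 CPM, among them every Hoxb gene of the list. Hoxa9 was 60.5 ± 9.1 CPM in control and 77.6 ± 14.4 CPM in Mt1ko, and Meis1 was 22.2 ± 3.4 and 21.1 ± 4.5 CPM. None of these passed the threshold (edgeR adjusted p = 1). Of the 19 B cell markers, 18 averaged under 1 CPM in control, as did 20 of the 22 T and NK cell markers. Other lineages were also seen: 11 of 25 neutrophil, 6 of 18 megakaryocyte and platelet, and 6 of 20 mast cell, basophil and eosinophil markers averaged at least 10 CPM in control.

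Over all genes, no gene was called between Mt1ko and control. The edgeR quasi-likelihood test gave 0 of 16666 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 171, of which 87 were higher and 84 lower, where chance alone gives 833. So few small p-values mean that the test was conservative here, and the lack of calls is not by itself evidence of no change. Samples of both groups also shared variation, described further on, and whether it was the source was not tested. limma-voom also called 0 genes, and the DESeq2 Wald test called 1, Mt1. Mt1 was also the gene called with 17 libraries entered singly and with library 6 left out. The groups did not overlap in 1184 genes, or 7.1%, where chance gives 10% for 3 against 3 samples. For 4688 of the 4955 genes with an average log2 CPM of 5 or more (94.6%), the 95% interval of the log2 fold change lay within 1 unit of 0, a difference of at most 2-fold. The same was so for 2869 of 11711 less expressed genes (24.5%). In simulated counts with the spread of these samples and 50 planted genes per fold size, the test recovered 32% of the genes changed 2-fold. It recovered 86% of those changed 4-fold and 92% of those changed 8-fold. In the real samples Mt1, with a log2 fold change of -1.85, was not called by the same test, which was conservative there. The simulated rates may therefore overstate what the test could find in these samples, and they do not show that changes of these sizes were absent.

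The genes with the smallest p in each direction are given as values, since none passed the threshold (edgeR adjusted p = 1 for each). They were chosen among genes with an average log2 CPM of at least 1, leaving out predicted loci, so scarcer genes may have had smaller p. Among the higher ones, Ccl3, a chemokine of inflamed myeloid cells, was 39.0 ± 2.4 CPM in control and 53.4 ± 3.6 CPM in Mt1ko, a log2 fold change of 0.45 (SE 0.13). Bcor, a corepressor that is mutated in some myeloid leukaemias, was 110.5 ± 10.4 and 152.4 ± 16.3 CPM, a log2 fold change of 0.46 (SE 0.14). Ttll1, Telo2 and Fam98c had log2 fold changes of 0.83, 0.75 and 0.59. Among the lower ones after Mt1 were Ccl25, a chemokine, at 20.6 ± 3.2 CPM in control and 12.5 ± 2.2 CPM in Mt1ko (log2 fold change -0.71, SE 0.23), and Odf2l, Tmem220 and Zfp382 with log2 fold changes of -0.51, -1.25 and -0.86. In each of these genes all 3 Mt1ko samples lay on the same side of all 3 control samples, as in 7.1% of all tested genes. Choosing genes by a small p favours such a separation, so it adds no evidence for them.

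Of the 30 gene lists with enough tested members, 1 was called. Mitochondrially encoded genes of oxidative phosphorylation were higher in Mt1ko (camera with a preset correlation, adjusted p = 1.37e-06), with 11 of 12 tested members higher and a median log2 fold change of 0.35. With an estimated correlation the call was lost (camera adjusted p = 0.92), as it was with fry (adjusted p = 0.98), and no member passed over all genes or adjusted over the list alone. The members with the smallest p were mt-Atp6 and mt-Atp8, subunits of ATP synthase, mt-Nd4l of complex I and mt-Co1 of complex IV, all on the mitochondrial genome. mt-Co1 was 4846 ± 809 CPM in control and 6898 ± 3725 CPM in Mt1ko (SD, n = 3 each), and its values in the Mt1ko samples were 4603, 11200 and 4896 CPM. mt-Atp6 was 8.92 to 52.2 CPM in the control samples and 178.6 ± 200.6 CPM in Mt1ko (SD, n = 3), with 53.03, 410 and 72.96 CPM in its samples, all above the controls. It overlaps mt-Atp8 in the annotation. mt-Nd4l was 1.48 to 14.95 CPM in the control samples and 12.8, 66.1 and 44.6 CPM in the Mt1ko samples. The list's median stood 0.95 log2 units above the control mean in Mt1ko sample 10-12, against -0.04 in sample 4-6 and 0.02 in sample 16-18. Without sample 10-12 the median log2 fold change was -0.02 and the list was not called (camera adjusted p = 0.28), while mt-Atp6 and mt-Nd4l had log2 fold changes of 1.16 and 1.80 and were not called (edgeR adjusted p = 1.00 for both).

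Libraries 10 to 12 stood apart from the other 14 in the same measures of RNA. Mitochondrial ribosomal RNA took 21.9% to 30.2% of their counts, against 4.6% to 11.2% in the others. They had 11548 to 13174 genes with at least 1 count, against 14823 to 17739. Spearman correlations among the 3 were 0.84 to 0.85. With these left out, the median over library pairs of 1 sample was 0.967. It was 0.956 over pairs from different samples of a group and 0.964 over pairs across the groups. By this correlation, libraries of 1 sample were hardly closer to each other than to libraries of other samples. The chi-square per gene parted them more. Its median was 52.9 over pairs of 1 sample, 121.4 over pairs from different samples of a group and 78.7 across the groups. The ranges of these pairs overlapped (32.4 to 162.5, 38.98 to 347.2 and 35.18 to 345.2). In the random effect fit over 17 libraries, the correlation of libraries within a summed sample was 0.18. Sample 10-12 also had the highest mast cell transcripts. Cpa3, which encodes a mast cell carboxypeptidase, was 1564 CPM there and 48.5 to 224.1 CPM in the other 5 samples, and Kit, the stem cell factor receptor, was 296.9 CPM there.

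**Figure D2:**
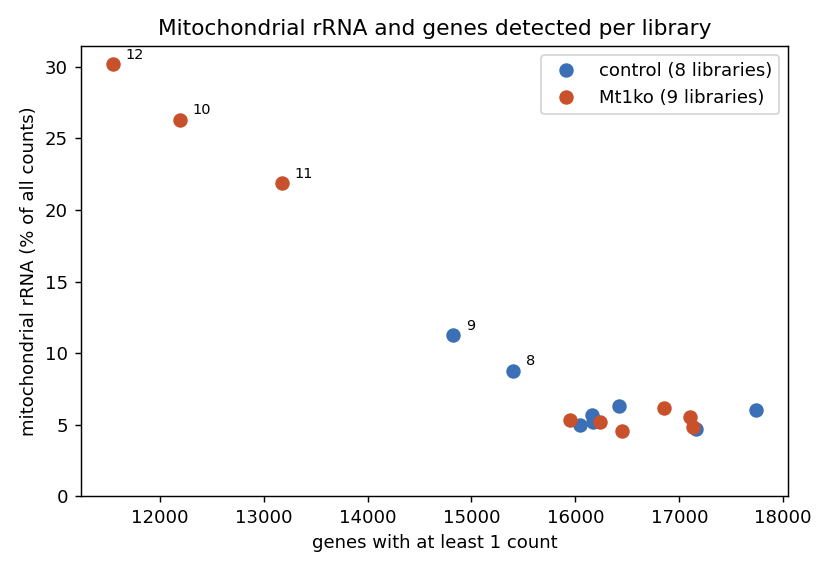
Share of all counts taken by mitochondrial ribosomal RNA (vertical, percent) against the number of genes with at least 1 count (horizontal) in 8 control (blue) and 9 Mt1ko (orange) libraries. Libraries 10 to 12 lie at 21.9% to 30.2% and 11548 to 13174 genes, apart from the other 14 libraries, which lie at 4.6% to 11.2% and 14823 to 17739 genes.

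The lists of metal handling and stress were not called. Of 24 tested metal-responsive and zinc transport genes, 11 were higher and 13 lower (median log2 fold change -0.02, camera adjusted p = 0.72). For the NRF2 oxidative stress list 19 of 25 were higher (median 0.06, camera adjusted p = 0.16), for the p53 targets 11 of 25 (median -0.04, adjusted p = 0.999), for the ferroptosis regulators 12 of 16 (median 0.07, adjusted p = 0.16), for the apoptosis regulators 9 of 20 (median -0.005, adjusted p = 0.999), and for iron and haem handling 13 of 20 (median 0.02, adjusted p = 0.53). Heat shock and proteostasis genes were higher in 12 of 15 (median 0.12, camera adjusted p = 0.10), and genes of the unfolded protein and ATF4 response were lower in 21 of 25 (median -0.10, adjusted p = 0.72). The median of the latter list was 0.177 without control sample 1-3. It was -0.399 without control sample 7-9, where camera called the list as lower (adjusted p = 4.44e-08), so its direction depended on the samples kept.

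Growth and metabolism lists were likewise not called by camera. Cell cycle genes were lower in 27 of 40 (median -0.10, adjusted p = 0.77), MYC targets higher in 19 of 27 (median 0.10, adjusted p = 0.16) and cytosolic ribosomal proteins higher in 13 of 30 (median -0.02, adjusted p = 0.999). Nuclear-encoded oxidative phosphorylation genes were higher in 23 of 33 (median 0.05, adjusted p = 0.19), glycolysis and hypoxia genes lower in 22 of 26 (median -0.09, adjusted p = 0.25), and cholesterol biosynthesis genes higher in 17 of 20 (median 0.09, adjusted p = 0.16). The interferon response was higher in 21 of 29 (median 0.17, adjusted p = 0.059), the inflammatory and NF-kB response in 18 of 30 (median 0.07, adjusted p = 0.16), the immediate early genes in 10 of 23 (median -0.07, adjusted p = 0.999) and the receptors of leukaemia growth signalling in 14 of 27 (median 0.01, adjusted p = 0.27).

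Leukaemic and lineage lists were not called by camera either. Members were higher in 10 of 15 for the HOX/MEIS programme (median log2 fold change 0.11, adjusted p = 0.34), 14 of 20 for stem and progenitor markers (0.20, adjusted p = 0.19), 12 of 21 for monocytes and macrophages (0.03, adjusted p = 0.72), 6 of 17 for neutrophils (-0.33, adjusted p = 0.34) and 7 of 16 for erythroid cells (-0.04, adjusted p = 0.37). The mast cell, basophil and eosinophil list had 8 of 10 members higher (1.60, adjusted p = 0.16), and the megakaryocyte and platelet list 11 of 12 (0.62, adjusted p = 0.063); in both, sample 10-12 stood highest, at 2.69 and 0.97 log2 units above the control mean. Dendritic cell, B cell, T and NK cell, and stroma and endothelium lists had 4 of 8, 2 of 5, 2 of 5 and 4 of 11 members higher (adjusted p = 0.72, 0.87, 0.87 and 0.87). Outside the metallothioneins, no list had a member that passed, over all genes or adjusted over the list alone.

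**Figure D3:**
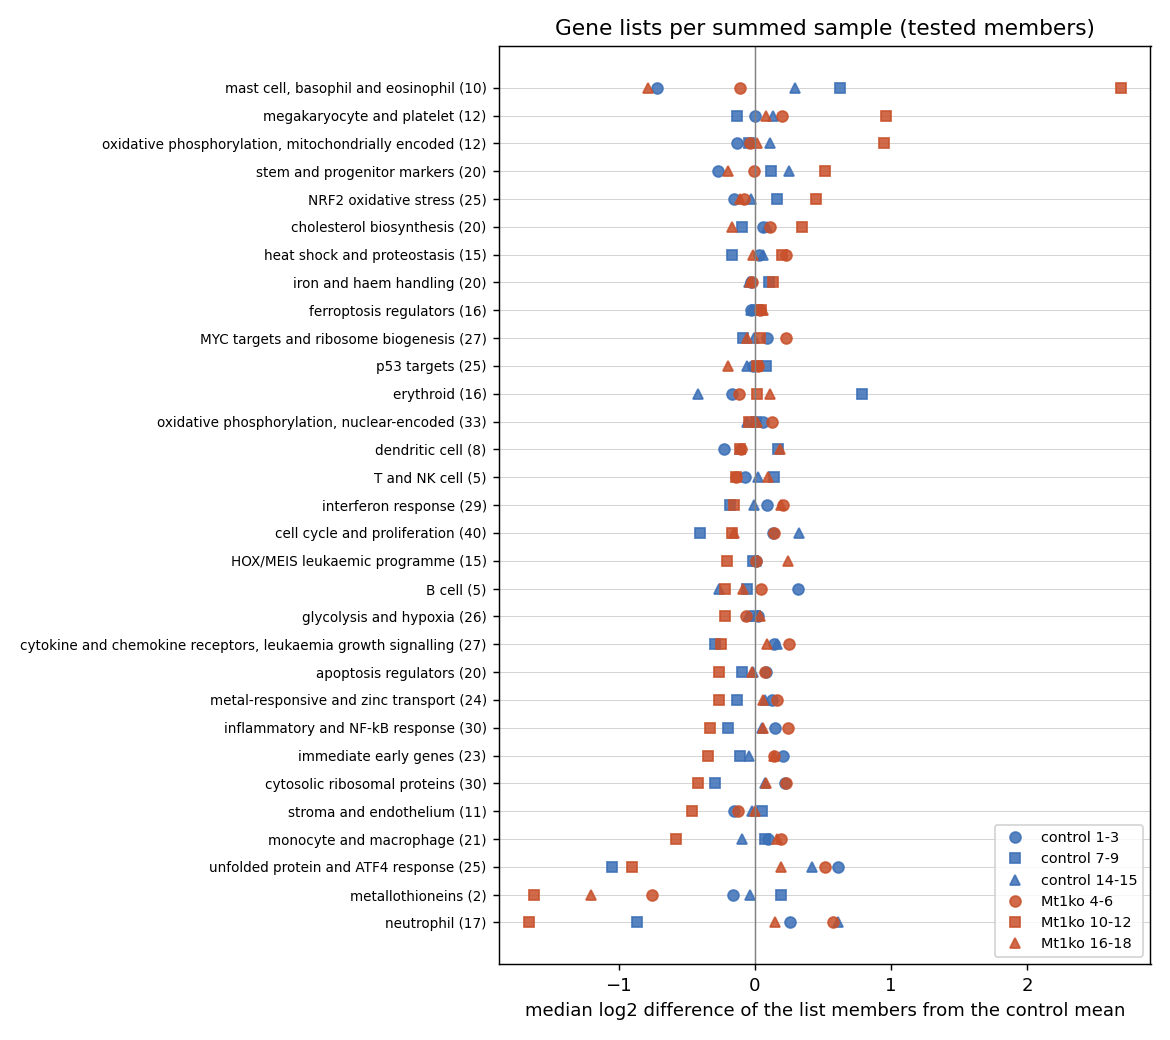
For each of the 31 gene lists, the median over its tested members (number in brackets) of the log2 difference from the control mean, in each of the 6 summed samples (blue control, orange Mt1ko; circles, squares and triangles mark the samples). Mt1ko sample 10-12 lies farthest from 0 in many lists, with 2.69 for mast cells and 0.95 for mitochondrially encoded genes, while Mt1ko samples 4-6 and 16-18 lie among the controls for the latter list.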

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

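Of 28 groups of library values examined, 4 held a library far from the rest of its group, and chance flags about 1 in 20. All tests of explanations in this part were chosen after the pattern had been seen. Mt1 was 326.2 CPM in library 6, labelled Mt1ko, where the next highest Mt1ko library held 87.2 CPM. The other 3 fell on library 11, labelled Mt1ko: Dnmt3a at 31.98 CPM (next 7.48), Xist at 305.1 CPM (next 139.1) and Kit at 413.2 CPM (next 194.0).

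The Mt1 level of library 6 was weighed first. A swap with a control library analysed here would have left a control library with low Mt1. In fact 0 control libraries were under 0.5 of the control median, which argues against such a swap. The library missing from the numbering was not analysed here, so a swap with it could not be examined. Control-level RNA would have to make up 80.8% of library 6 to give its Mt1 level, if the rest were like the other Mt1ko libraries. No other gene was called between the groups, so no second gene can place the library. Unedited cells, RNA of another sample and a wrong label are among the possible sources, and they cannot be told apart. The RNA level alone does not show whether the gene was edited in library 6. Its mean Spearman correlation was 0.976 with libraries 4 and 5 and 0.970 with control libraries 1 to 3.

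The mitochondrially encoded list was weighed second. As an effect of the Mt1ko group on the list as a whole it would appear in samples 4-6 and 16-18 too, but their mean shift was -0.008 log2 units, with a control SD of 0.121, and without sample 10-12 the quartiles of the 12 members were -0.079 and 0.087, below the median of 0.35, which argues against that. It does not settle mt-Atp6 and mt-Nd4l. Their log2 fold changes without sample 10-12 were 1.16 (95% interval -0.199 to 2.52) and 1.80 (-0.116 to 3.71). However, mt-Atp8, which overlaps mt-Atp6 in the annotation, was then at 0.006 (-0.324 to 0.336), and mt-Nd4 at -0.012 (-0.33 to 0.306). Of the 12 members, 4 were higher in that fit. With the random effect over 17 libraries mt-Atp6 was at -0.10 and mt-Nd4l at 0.192. How reads shared by overlapping genes were counted is not given in the sources used here. An effect of the group on mt-Atp6 and mt-Nd4l is thus not shown, and it stays open. A link to low complexity of libraries 10 to 12 was tested in the control libraries, where the list's share of counts and the number of genes detected had a Spearman rho of -0.571 (exact permutation p = 0.151, n = 8) and a Pearson r of -0.51 (exact permutation p = 0.191, n = 8). Without the 2 libraries farthest from the median of genes detected, r was -0.087, so the relation rests on them. Low complexity may be the source of the shift in the list, and 8 libraries of 3 samples do not decide it; a state of the cells in that 1 sample stays open too.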

How the results depend on the processing

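The alternatives that left out library 6, alone or with libraries 10 to 12, left out mitochondrial genes, weighted samples or used a random effect were chosen after the data had been seen. No paired analysis was run, because the groups share no replicate numbers and no label ties a control sample to an Mt1ko sample. The order of the libraries was not taken as a pairing, so what a fit on neighbouring samples would give was not tested. The count of 0 genes called by edgeR was also 0 in 16 of 21 alternatives, including every one that left out a sample (0 to 0). It was 1, Mt1 each time, with 17 libraries, DESeq2, the random effect, library 6 left out, and libraries 6 and 10 to 12 left out. The log2 fold change of Mt1 was then -1.90, -1.84, -2.08, -2.30 and -2.21, with adjusted p from 8.03e-05 to 0.015. With the second index as a covariate it narrowly missed (edgeR adjusted p = 0.054). Mt1 kept its direction in all 19 alternatives, from -2.37 to -1.60, which is also the range on leaving out a sample, and its adjusted p ran from 8.03e-05 to 1. Mt2 ran from -0.57 to -0.24 in 19 alternatives and was called in none. The number of lists called by camera, 1, was 3 with upper quartile scaling, 2 without a filter, 9 with 17 libraries, 12 with the second index added, 0 with an estimated correlation, 0 with fry, 2 without library 6, 5 without libraries 6 and 10 to 12, and 2 to 8 on leaving out a sample. The mitochondrially encoded list had a median of 0.35 and was not called with the estimated correlation or fry. Its median ran from -0.019 to 0.533 on leaving out a sample, and was -0.09 without libraries 6 and 10 to 12. The 15 other named genes stayed uncalled in 281 comparisons, 273 of them in the main direction. Reversals were Dnmt3a and mt-Co1 without sample 10-12 (ranges on leaving out a sample -1.06 to 1.83 and -0.026 to 0.727), Dnmt3a at -1.23, mt-Atp8 at -0.09 and mt-Co1 at -0.089 without libraries 6 and 10 to 12, mt-Atp6 at -0.10 with the random effect, and Dnmt3a at -0.90 and mt-Co1 at -0.030 with sample weights, which gave sample 10-12 a weight of 0.177. The causes of changes other than fewer samples were not tested. Depth and spread limit genes of low expression most, such as Dnmt3a at 2.70 CPM in control.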

Other observations

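All tests in this part except the counts of splits of the 6 full samples and of the drawn splits of 17 libraries were chosen after the patterns had been seen. Control sample 7-9 and Mt1ko sample 10-12 shared a profile that crossed the groups. The list of the unfolded protein and ATF4 response stood at -1.05 and -0.90 log2 units from the control mean in these samples, and at 0.19 to 0.61 in the other 4. The neutrophil list stood at -0.87 and -1.66, against 0.15 to 0.61. Chil3, a chitinase-like protein of myeloid cells, was 49.2 and 63.0 CPM, against 1468 to 1904 CPM. Elane, the neutrophil elastase, was 6.7 and 1.4 CPM, against 27.0 to 80.0 CPM. Mrc1, the macrophage mannose receptor, was 12.2 and 19.9 CPM, against 164.1 to 305.0 CPM. Over 8773 genes, the deviations of these samples from their group means correlated at 0.475, a correlation across genes, which are not independent replicates. For the neighbouring samples 1-3 and 4-6 the correlation was 0.441, and for 14-15 and 16-18 it was 0.107. Sample 14-15 correlated more with 4-6, at 0.272, and 16-18 more with 1-3, at 0.371. Whether neighbouring samples were prepared side by side is not given in the sources used here, so their order was not used to pair them.

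With libraries 6 and 10 to 12 left out, camera called the inflammatory and NF-kB response (adjusted p = 2.19e-06, median log2 fold change 0.22), the interferon response (adjusted p = 0.0011, median 0.29), monocyte and macrophage markers (adjusted p = 0.021, median 0.20) and cytosolic ribosomal proteins (adjusted p = 0.00054, median 0.15) as higher, and the mast cell list as lower (adjusted p = 0.0050, median -1.003). None of the 5 calls held with an estimated correlation (camera adjusted p = 0.72 for each). Over all 16 alternatives, the interferon response was called as higher in 7, the inflammatory response in 4 and monocyte markers in 1, and none of these as lower in any. The calls without libraries 6 and 10 to 12 kept control sample 7-9, which shared a profile with sample 10-12. With control sample 7-9 left out instead, none of these lists was called. The medians were then 0.084 for interferon, -0.026 for the inflammatory response and -0.156 for monocyte markers (camera adjusted p = 0.41, 0.96 and 0.81). The direction of the last 2 lists thus depended on the samples kept. The mast cell list was called as higher in 3 and lower in 1, and cytosolic ribosomal proteins as higher in 2 and lower in 1, so neither had a steady direction.

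Xist, the RNA that coats the inactive X chromosome, varied from 0 counts in library 16 to 305.1 CPM in library 11 and followed the mast cell list. Over 17 libraries the Pearson r of log2 values was 0.942 and the Spearman rho 0.944 (permutation p = 1e-05 for both, the smallest the resamples give; adjusted over 9 relations 9e-05). Without the 2 libraries farthest from the median of Xist, r was 0.928. Libraries of a sample are not independent, and over the 6 summed samples r was 0.990 (exact permutation p = 0.00278) and rho 0.943 (exact permutation p = 0.0167), with adjusted values of 0.005 and 0.025. The 9 relations overlapped in their libraries. The mast cell list was picked among 28 scored lists after the pattern had been seen, and the adjusted values do not correct for that choice. Values within subsets of the libraries are given without p-values, since few samples stood behind each subset. Within the 8 libraries of the first index sequence r was 0.884 and rho 0.905, and within the 7 of the second 0.956 and 0.857. In 8 control libraries r was 0.920 and rho 0.833, and in 9 Mt1ko libraries 0.977 and 0.917. Without libraries 10 to 12, r was 0.903 and rho 0.912 over 14 libraries. Cells with mast cell transcripts in varying share may be the source, as a hypothesis; of the 8 genes in the list score, Cpa3, Tpsb2 and Cma1 had a rho of 0.912 with Xist there, Fcer1a 0.908, Ms4a2 0.881 and Gata1 0.735, while Ccr3 had 0.013 and Il6ra -0.349. However, the list of stem and progenitor markers, with Kit, Gata2 and Cd34, had 0.947, so a mast cell or progenitor source is open. Members of that list did not move as one. In sample 10-12, Kit, Gata2, Cd34 and Ly6a were the highest of the 6 samples. Cd48 was the lowest, at 6.24 CPM against 9.50 to 19.4 CPM, and Myb and Cdk6 lay within the range of the others. Low library complexity as the whole source is argued against by the partial rho of Xist and the mast cell list given genes detected, which was 0.909 over the same 14 libraries and 0.882 to 0.936 on leaving out 1 library; over 17 libraries it was 0.921. Xist and genes detected themselves had a rho of -0.178 and an r of -0.332 over the 14, and of -0.525 and -0.667 over 17 libraries. Xist was thus higher where fewer genes were detected once libraries 10 to 12 were included.

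The Y-linked genes Ddx3y and Eif2s3y had 0 counts in all 17 libraries, out of all counts of the series, where 3 counts would be 0.00546 CPM. Uty had 41 counts and Kdm5d 298 over all libraries. Library 16 had 0 Xist counts, which allows up to 0.111 CPM at that depth, and 3657 CPM of Lyz2. Whether the monocytic cells carry an inactive X chromosome was not tested.

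As a check on chance, other splits of the samples were compared with the real one. The 6 samples make 10 splits, too few for a share under 0.05: the real split called 0 genes and the highest other 0, so 10 of 10 had as many. For lists the real split called 1 and the highest other 12, and 10 of 10 had as many. All 4 splits that placed samples 7-9 and 10-12 together called 10 to 12 lists (1 that parted them called 11), which points to a structure of the samples. Without library 6, which was left out because of its Mt1 value, the real split called 1 gene, Mt1, and the highest other 0 (1 of 10, again too few). Of 100 drawn splits of the 17 libraries, the real one included, only it called a gene (1, highest other 0; 1 of 100), but these splits break up the samples and take libraries of a sample as independent, so they decide nothing. Splits of the 17 libraries that keep each sample whole number 10, too few for a share under 0.05: the real one called 1 gene and the highest other 781, and 3 of 10 had as many. The 2 others called 287 and 781 genes, against 1 in the real split, which points to a structure of the samples. Both placed samples 7-9 and 10-12 together, but the 2 remaining splits that did so called 0 genes, so that structure is not these samples alone.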
